A study of Homo sapiens with 5 samples.

How the data were processed

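The series measured K562 cells with 2 csRNA-seq libraries, 2 libraries of input small RNA and 1 RNA-seq library, with each library cut to 1000000 reads per the labels. HOMER, STAR and hg38 are named per the submitters' processing notes, and the settings of the aligner and of the caller are not given in the sources used here. The single deposited table listed start-site clusters, most of them 150 bp wide (23553 of 23569), with 1 column per library kind, so replicates were not separated, and whether they were combined is not stated.

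The signal values of the csRNA, input and RNA columns were scaled by the authors to reads per 10000000. The score of each cluster, per the file headers a caller value, lay within 0.1 of its csRNA value in 20205 of 23569 clusters and was not used further. The focus ratio is a fraction, deposited by the authors, of reads near the main start of the cluster, and the extent is not stated. The deposited log2 ratios of the authors were formed with a pseudocount of 1: 3 of these columns (to input, to RNA and between strands) were recomputed from the signal within 0.001 for all 23569 clusters. The authors' classes (stable or unstable, bidirectional or unidirectional, proximal or distal) were used as deposited, and what each class meant was read from the values: at least 1 against 0 RNA reads in the wider window, at least 1 against 0 csRNA reads on the opposite strand, and at most 500 bp against at least 501 bp from an annotated start.

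Whole reads were recovered by multiplying each value by the depth fitted to its column (486100, 747700 and 809700 reads) over 10000000, which makes 1 read 20.57 for csRNA, 13.37 for input and 12.35 for RNA after rounding, and 100% of values were whole within 0.1 reads. At this depth a value of 0 was read as under 3 reads, that is under 61.7 for csRNA, 40.1 for input and 37.1 for RNA, and a fold against 0 is given as a lower bound from that floor. Shares have Wilson intervals, single values exact Poisson intervals and folds exact binomial intervals, all at 95%. Medians and differences between classes of clusters have intervals from 10000 resamplings of whole chromosomes. In the closing section, intervals of medians and their ratios instead came from 10000 redraws of single clusters, as if these were independent. The interval of the difference in stable share there came from the ends of the Wilson intervals. No p-value was computed, because there was no replicate spread.

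Genes were named from the accession beside the annotation through a table of RefSeq symbols (GRCh38.p14, 59792 genes). This named 9241 of 9280 sense promoter clusters (99.6%), and the gene differed from the nearest symbol in 275. The csRNA value of a gene is the sum of its sense promoter clusters, and its RNA value the highest wider-window RNA value among them. Gene lists, 23 in all, were fixed: globin, haem synthesis, erythroid, megakaryocyte, granulocyte and monocyte, lymphoid, hepatocyte, neuron and glia, fibroblast and epithelium, ribosomal protein, translation factor, histone, snoRNA host, immediate early, heat shock, cell cycle, oxidative phosphorylation, zinc finger, small nuclear RNA (with 7SK, 7SL and RMRP), snoRNA, long noncoding RNA, K562 and 9p21 genes. Each list of at least 5 genes with a cluster was placed among 10000 random lists of the same size. For RNA over csRNA these were matched on 10 bins of csRNA. Detection was placed among random protein-coding genes, for lists of protein-coding genes only.

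Genes and clusters were named by a rule: the 10 highest proximal and 5 highest distal clusters, the 5 with the highest input, the 8 highest and 8 lowest genes by RNA over csRNA in the upper 50% of csRNA, and up to 4 members per list with its missing members. Some of the genes and clusters that the rule picks are not reported here. Clusters of the beta-globin locus, the NPRL3 intron and 9p21 were named beyond the rule, as was any gene of the closing section. Alternatives were written down before the data were examined for pseudocounts, filters on csRNA value, distance limits, the RNA threshold, partners on the opposite strand and the value per gene. Others were added afterwards: clusters with input only, RNA within the cluster, 0 RNA reads set at 3 reads, 32 or more csRNA reads, 2 or more opposite-strand reads, clusters without small RNA genes, and genes by nearest symbol. The planned count test of csRNA against input by library was not run because the table had no column per library, and the planned study of sequence at start sites was not run because no genome sequence was used here.

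The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data: reads were recovered exactly for 100% of 23569 clusters, lists of 20 genes lay above the 97.5th percentile in 0 of 10 cases with no simulated difference, 4 of 10 at 2-fold and 8 of 10 at 4-fold (8894 genes), and chromosome resampling intervals held the simulated share in 92 of 100 runs (23540 clusters).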

Results

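Capped small RNA sequencing (csRNA-seq) reads the short RNAs that carry a 5′ cap and so marks where RNA polymerase II has just started, including at short-lived transcripts such as enhancer RNAs. It was applied to K562, a human erythroleukaemia cell line that carries the BCR-ABL1 fusion and expresses embryonic and fetal globins. The series held 5 libraries: 2 of csRNA-seq, 2 of input small RNA, which is the same size fraction without cap enrichment, and 1 of RNA-seq. The comparison named by the design set csRNA-seq against input small RNA to find nascent RNAs. The deposited table gave 1 value per library kind for each start-site cluster, in reads per 10000000, so no value had a replicate error and the differences below have no replicate check. A single csRNA read was worth 20.57 in these units, an input read 13.37 and an RNA-seq read 12.35, which corresponds to about 486100, 747700 and 809700 reads in total. Reads that PCR copied from the same molecule are not independent, so real errors are wider than counting errors. Intervals on single values are exact Poisson or binomial 95% intervals from these recovered reads and cover counting error only. Coordinates are on hg38.

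The table listed 23569 start-site clusters, of which 23540 lay on chromosomes 1 to 22 and X. The authors classed 14235 (60.4%, Wilson 95% interval 59.8 to 61.0%) as promoter-proximal, which in the table meant within 500 bp of an annotated transcript start, and 9334 (39.6%) as distal. Of the proximal clusters, 9280 started in the direction of an annotated gene, at its first or single exon (sense promoter clusters), 4153 ran antisense to the gene at the promoter, and 802 lay elsewhere within the 500 bp. Distal clusters lay a median of 15.9 kb from the nearest annotated start. Clusters were shallow at this depth: the median cluster held 5 csRNA reads, and 50.1% of clusters held at most 5.

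The highest csRNA values of promoter-proximal clusters were at genes for small nuclear RNAs and histones. U5 spliceosomal RNA genes took the first places. RNU5A-1 (chromosome 15, 65295976 to 65296126, + strand) had a csRNA value of 178243 (95% interval 174509 to 182037), RNU5F-1 (chromosome 1, 44721828 to 44721978, - strand) 95149 and RNU5E-1 (chromosome 1, 11908077 to 11908227, + strand) 82559. RNU7-1, which encodes the U7 RNA that processes histone messages, followed at 70853 (chromosome 12, 6943742 to 6943892), and SNORD43, an intronic small nucleolar RNA, at 63879 (chromosome 22, 39319007 to 39319157). The histone H3 genes H3C2 (54600, chromosome 6, 26032024 to 26032174) and H3C10 (44972, chromosome 6, 27809976 to 27810126) were next, and then C19orf48P (42339), the ribosomal protein gene RPS27 (31908) and PPP1R10 (29645), a regulatory subunit of a protein phosphatase. Small nuclear and nucleolar RNA genes and histone genes have near-identical copies, so the value of a single copy is uncertain. Reads were concentrated near the main start in most of these clusters: the authors' focus ratio, a fraction, was 0.989 at RNU5A-1 and 0.997 at H3C10, against 0.761 at RNU7-1 and 0.757 at SNORD43.

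The highest distal clusters lay below the leading U5 genes but within the range of the 10 highest proximal clusters or close to it. The first, at 75523 on the - strand of chromosome 11 (59626944 to 59627094), lay in the noncoding gene LOC101927226, 11245 bp upstream of OSBP, and had 0 RNA reads. Another, at 39850, lay on chromosome 17 (43315841 to 43315991), 15685 bp upstream of RNU2-1, a U2 spliceosomal RNA gene. Further ones were at 30016 within TEX14 and LOC124904154 (chromosome 17, 58631761 to 58631911) and at 27341 on chromosome 1 (16905124 to 16905274), 9219 bp from the U1 variant gene RNVU1-18. Clusters over small RNA genes and their copies made up 137 of the distal clusters and held 9.89% of distal csRNA reads. At proximal sites 85 such clusters held 12.3% of the reads.

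csRNA reads were concentrated in the listed clusters and input reads were not. The clusters held 74.8% of csRNA reads (Wilson 95% interval 74.7 to 74.9%), 2.16% of input small RNA reads (2.13 to 2.20%) and 0.47% of RNA-seq reads (0.456 to 0.485%), a 34.6-fold difference between the csRNA and input shares. The lowest log2 ratio to input in the authors' deposited table was 1.19, so enrichment over input was a property of every listed cluster and not an independent result. No input read fell in 71.9% of clusters, and among the 6612 clusters with at least 1 input read the median csRNA value was 15.4 times the input value (quartiles 8.20 and 27.7). This median was 20-fold at sense promoter clusters, 13.8-fold at antisense promoter clusters and 10-fold at distal clusters, which rests on 1753 of 9334 distal clusters. This order did not hold for reads summed over all clusters of a class, with 33.2-fold at sense promoter, 35.1-fold at antisense promoter and 38.8-fold at distal clusters, and without clusters at small RNA genes the summed folds of proximal and distal clusters were alike (38.1 and 38.3). Over all clusters the median log2((csRNA + 1)/(input + 1)) was 5.97, a value set by the pseudocount because most inputs were 0: it was 4.13 with a pseudocount of 5.

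The 5 clusters with the most input were all at small noncoding RNA genes, and their csRNA enrichment differed. SNORD43 had an input value of 6406 and a csRNA value 9.97 times as high (exact 95% interval 9.05 to 11). RNU7-1 had 4775 and 14.8-fold (13.3 to 16.6), and RNU12, the U12 RNA of the minor spliceosome, 3558 and 6.86-fold (6.0 to 7.86). RMRP, the RNA of RNase MRP, which RNA polymerase III transcribes, had 4735 and 3.73-fold (3.29 to 4.23). SNORD95, an intronic small nucleolar RNA, had 2996 and the smallest ratio of the 5, 2.47-fold (2.09 to 2.93). By contrast the 3 leading U5 genes were enriched 76.6-fold at RNU5A-1, 60.3-fold at RNU5F-1 and 92.1-fold at RNU5E-1.

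Promoter-proximal start sites had higher csRNA values than distal ones. The median csRNA value was 164.58 at proximal clusters (95% interval 144.01 to 164.58 from resampling whole chromosomes) and 82.29 at distal clusters (61.72 to 82.29), that is 8 against 4 reads, a 2.0-fold difference (1.75 to 2.67). The proximal value was 185.16 at sense promoter clusters and 123.44 at antisense promoter clusters. Proximal clusters held 77.2% of the csRNA reads in clusters and sense promoter clusters alone 63.4%. Clusters and chromosomes are not biological replicates, so these intervals describe the spread over loci in these libraries.

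Stable transcripts separated gene starts from the other start sites. The authors' stable class was equivalent in the table to at least 1 RNA-seq read in a window wider than the cluster, whose extent is not given in the sources used here. It held 72.5% of sense promoter clusters (Wilson 95% interval 71.5 to 73.4%), 12.3% of antisense promoter clusters (11.3 to 13.3%) and 10.97% of distal clusters (10.4 to 11.6%). Sense promoter clusters exceeded antisense ones by 60.2 percentage points (57.7 to 62.5, chromosome resampling), whereas antisense promoter clusters and distal clusters differed by 1.29 points (-0.30 to 2.75), an interval that includes 0. With at least 2 RNA reads required, the shares were 54.7%, 3.68% and 4.54%, and antisense promoter clusters lay below distal clusters by a small margin (-0.86 points, -1.68 to -0.06). The stable share was higher where csRNA was higher: at sense promoters it was 53.7% among clusters with 2 to 3 csRNA reads and 88.8% among those with 32 or more, and at distal clusters 7.2% and 28.6%.

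**Figure D1:**
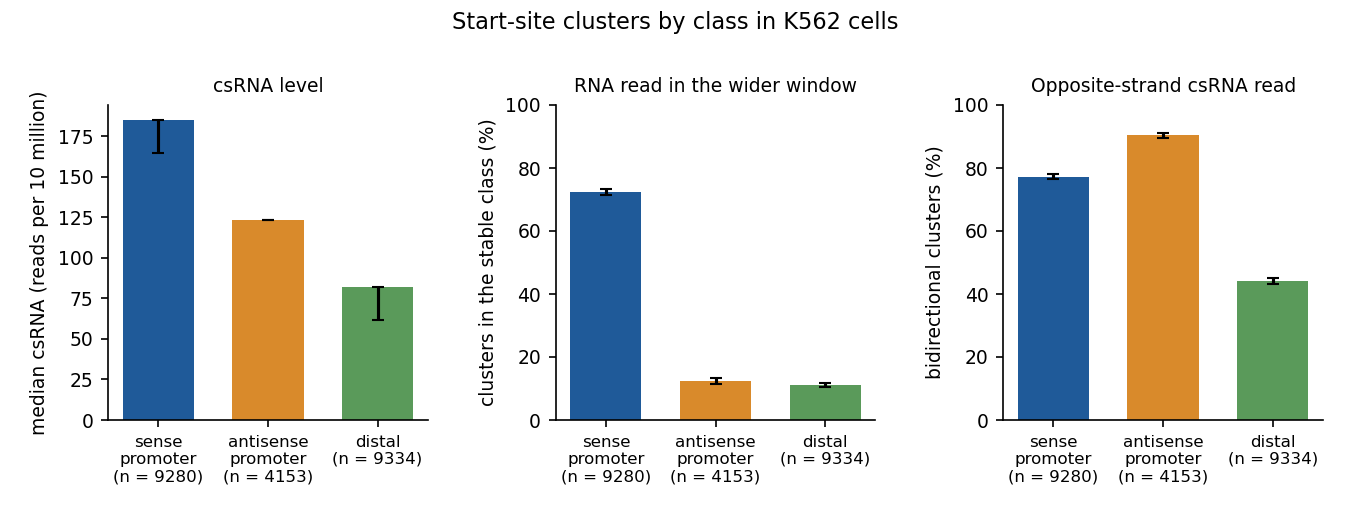
Median csRNA value in reads per 10000000, percentage of clusters in the stable class and percentage of bidirectional clusters, for 9280 sense promoter, 4153 antisense promoter and 9334 distal clusters. Error bars on medians are 95% intervals from chromosome resampling and those on percentages Wilson 95% intervals; the stable share was 72.5% at sense promoters against 12.3% and 10.97% in the other classes.

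Initiation on both strands was more common at promoters than at distal sites. The authors' bidirectional class, which in the table meant at least 1 csRNA read on the opposite strand, held 80.7% of proximal clusters (Wilson 95% interval 80.1 to 81.3%) and 44.0% of distal clusters (43.0 to 45.0%), a difference of 36.7 percentage points (34.1 to 39.3, chromosome resampling). With a listed opposite-strand cluster within 300 bp upstream required instead, the shares were 46.6% and 15.5%. It held 77.3% of sense and 90.3% of antisense promoter clusters. Where a sense promoter cluster had another cluster on the opposite strand within 500 bp upstream, which was so for 53.1% of them, the start sites lay a median of 181 bp apart (quartiles 122 and 272). Distal clusters had such a partner in 18.1% of cases, at a median spacing of 151 bp. Among bidirectional clusters, the authors' configuration was unstable on both strands for 74.4% of distal clusters (73.0 to 75.7%) and for 21.4% of proximal clusters, and stable on both strands for 2.0% of distal and 14.7% of proximal clusters. Clusters at small RNA genes were bidirectional in 26.1% of cases (20.8 to 32.3%).

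**Figure D2:**
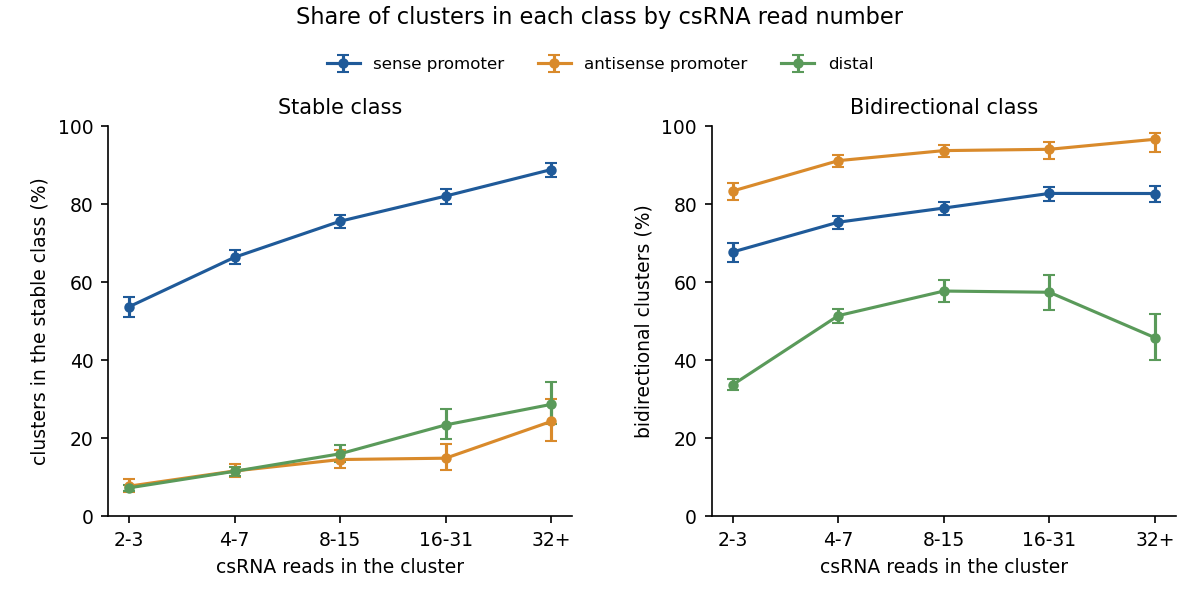
Percentage of clusters in the stable class (left) and in the bidirectional class (right) by the number of csRNA reads in the cluster, for sense promoter, antisense promoter and distal clusters. Points are shares and bars Wilson 95% intervals; the stable share at sense promoters runs from 53.7% at 2 to 3 reads to 88.8% at 32 or more, and the bidirectional share of distal clusters is 33.7% at 2 to 3 reads, highest at 57.7% at 8 to 15 reads and 45.7% at 32 or more.

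Genes of haem synthesis and of the erythroid lineage were represented among the promoters, while most markers of other lineages were not. A sense promoter cluster was listed for 8894 genes, including 7967 of 19974 protein-coding genes (39.9%, Wilson 95% interval 39.2 to 40.6%). Of the 9 haem synthesis genes, 8 had one. ALAS1, which encodes an enzyme of the first step, and UROD were both at 1008 (95% interval 746 to 1333) and PPOX was at 494, and UROS had none. ALAS2, the erythroid form of the first enzyme, was the lowest of the 8 at 82.29 (4 reads), with 0 RNA reads. Of 22 genes for erythroid membrane proteins and regulators, 15 had a cluster: TFRC, the transferrin receptor, was at 3251, the transcription factor NFE2 at 1852 and RHAG of the Rh complex at 1543. BCL11A, EPB42 and ZFPM1 were among those with none in the table used here. The numbers of members detected were at percentiles 99.8 and 99.6 of 10000 random draws of protein-coding genes. Cell cycle genes (24 of 26) and heat shock genes (15 of 16), which mark no lineage, were also detected more than random draws. A high percentile therefore does not by itself show lineage.

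By the same count, hepatocyte markers were detected for 1 of 15 genes (TF, the transferrin gene, at 247), lymphoid markers for 2 of 18 (CD3D at 185 and RAG1 at 82.29), granulocyte and monocyte markers for 2 of 15 (CEBPA and LYZ, both 164.58) and neuron and glia markers for 2 of 15 (TUBB3 at 123.44 and GAD1 at 61.72). Their percentiles were 0.24, 0.42, 1.65 and 1.75. Detection of fibroblast and epithelial markers (3 of 14, led by the keratin genes KRT8 at 617 and KRT18 at 103, with EPCAM at 41.15) and of megakaryocyte genes (3 of 13, with GP1BB at 1646, TUBB1 at 329 and GP6 at 123.44) lay within the range of random lists, at percentiles 8.55 and 11.35. Among the megakaryocyte genes without a cluster were ITGA2B, ITGB3 and PF4. None of the 7 genes of the chromosome band 9p21 list (CDKN2A, CDKN2B, MTAP, IFNA1, IFNB1, KLHL9 and DMRTA1) had a cluster, at percentile 1.58. These genes are neighbours, whereas the random draws treat genes as independent, so this percentile may be too extreme.

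Of the 10 globin genes, 3 had a promoter cluster, at percentile 27.6 and so within the range of random lists. HBE1, the embryonic epsilon globin, had a csRNA value of 3292 (95% interval 2801 to 3843) and an RNA value of 5150 (4668 to 5669) at chromosome 11, 5269870 to 5270020, on the - strand. HBQ1 was at 226 (113 to 405) and HBZ, the embryonic zeta globin, at 206 (98.7 to 378). Both clusters lay inside the gene, 101 bp (HBQ1) and 211 bp (HBZ) downstream of the annotated start. Their input values were 26.75 and 66.87, so initiation at the annotated HBQ1 and HBZ starts is not shown. No cluster in the table used here lay within 500 bp of HBA1, HBA2, HBG1, HBG2, HBB, HBD or HBM. Upstream of HBE1, in the stretch that holds the locus control region of the beta-globin genes, 5 distal clusters were listed between 5275996 and 5288410, with csRNA values from 61.72 to 206 (3 to 10 reads). A distal cluster of 4 reads lay in an intron of NPRL3 (chromosome 16, 113301 to 113451), the gene that contains the upstream regulatory elements of the alpha-globin genes.

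**Figure D3:**
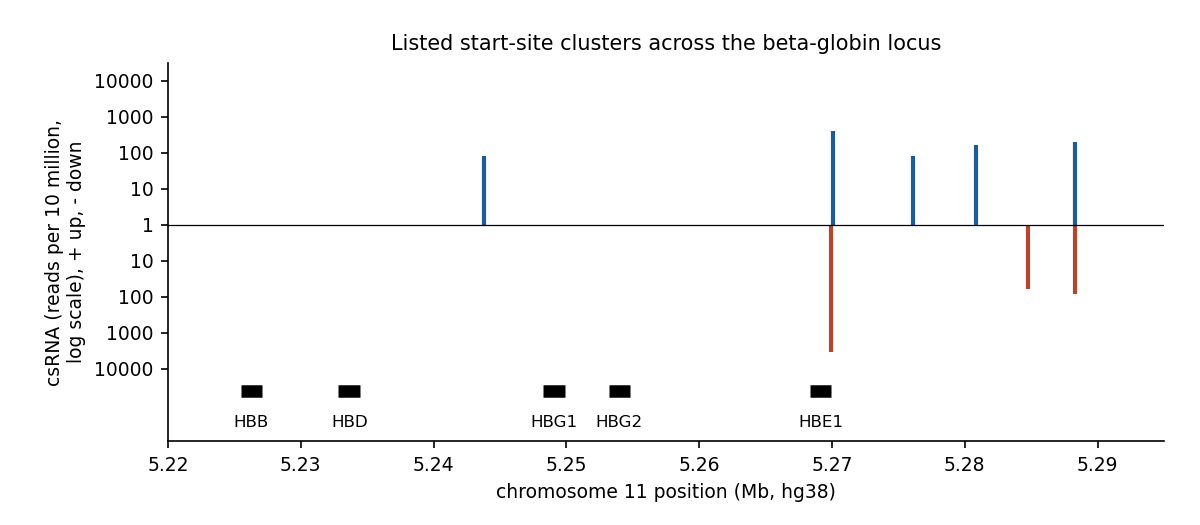
Listed start-site clusters across the beta-globin locus on chromosome 11 (hg38 position in Mb on the x axis); the height of each line is the csRNA value in reads per 10000000 on a log axis, with + strand clusters upward and - strand clusters downward, and black bars are the genes. The highest line, at 3292, is the HBE1 promoter, next to the + strand cluster of the same promoter at 411; the 5 distal clusters further to the right reach at most 206.

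Promoters of growth-related genes carried more csRNA than random lists of genes. Replication-dependent histone genes had clusters for 41 of 68 members with a median csRNA value of 3107, and ribosomal protein genes for 78 of 84 with a median of 1358. Both exceeded all 10000 random lists of the same size, as did the cell cycle (24 of 26 genes, median 710), oxidative phosphorylation (74 of 86, median 535) and snoRNA host gene lists (24 of 34, median 874). The leading ribosomal protein genes after RPS27 were RPS14 at 27876, RPL13 at 22712 and RPS29 at 21272. The leading snoRNA hosts were SNHG3 at 23453 and ZFAS1 at 12035, and SNHG5 (8250) and DANCR (8147) followed. The leading histone genes after H3C2 and H3C10 were H2AC11 at 29172 and H2AC12 at 23988. Translation factors (19 of 20, median 555, led by EIF4A2 at 18474) and heat shock genes (15 of 16, median 597, led by the chaperone genes DNAJA1 at 11829, HSPA1A at 8867 and HSP90AB1 at 8743) were at percentile 99.9 of csRNA level. Zinc finger genes lay at the other end in csRNA level, with a median of 144 at percentile 0.08, although more of them had a cluster (310 of 509) than in any random list.

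The spliceosomal and other small nuclear RNA list had 28 of 49 members with a cluster (median 1646), while only 30 of 568 small nucleolar and Cajal body RNAs had one (5.28%, Wilson 95% interval 3.72 to 7.44%). The latter included SNORD43, SNORD75 (18845), SNORD138 (15018) and SNORD136 (14771). The 6 detected genes of the K562 list had a median of 2314, above all random lists. PRAME, a tumour antigen, was at 14566 (95% interval 13512 to 15679; chromosome 22, 22557517 to 22557667), the fusion partner BCR at 2839 (2385 to 3354; chromosome 22, 23180463 to 23180613), NUP214 at 2448 and CRKL at 2181. ABL1 and IGLL5 had no cluster.

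RNA-seq signal beside the start site set the lists apart from one another. Over the 8894 genes the median log2((RNA + 1)/(csRNA + 1)) was -3.22 (95% interval -3.35 to -3.12, chromosome resampling), and 26.5% of genes had 0 RNA reads. The RNA value covers only the window near the start, so it also depends on how the first exon lies in that window and is not the expression of the whole gene. Across genes csRNA and RNA had a Spearman correlation of 0.36, with genes not being independent replicates. Against 10000 random lists matched on csRNA level, ribosomal protein genes (median log2 ratio -1.19, random median -4.22), translation factors (-1.35), replication-dependent histones (-1.96) and oxidative phosphorylation genes (-1.78) had more RNA per csRNA than every random list. Examples were NPM1 (csRNA 2469, RNA 1976), UQCRH (6686 and 2433) and COX5B (3251 and 1198). The ribosomal protein genes with the highest csRNA lay far below their list's median, with log2 ratios of -5.97 at RPS27 and -4.45 at RPS14. Heat shock genes (-2.17, percentile 99.4), long noncoding RNAs (8 of 14 genes, -1.56, percentile 98.9) and cell cycle genes (-2.64, percentile 98.99) also lay above, the last only while 0 RNA reads were kept with the pseudocount: with 0 set at 3 reads they were at percentile 94.96.

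Immediate early genes and zinc finger genes had little RNA for their csRNA. Of the 24 immediate early genes, which encode short-lived messages induced by growth signals and stress, 17 had a cluster, with a median csRNA value of 391, and 7 of the 17 had 0 RNA reads. EGR1 was at 3559 with 0 RNA reads, at least 96.1-fold more csRNA than RNA. DUSP1 was at 1975 with 0 RNA reads, at least 53.3-fold. IER5 was at 2983 against an RNA value of 98.81 and JUN at 1584 against 37.05. The list's median log2 ratio of -5.38 was at percentile 2.12, but at 2.84 with a pseudocount of 5 and 3.65 with 0 RNA reads set at 3 reads, both inside the central 95% of random lists. Zinc finger genes had a median of -4.54, below all random lists (random median -3.08), with 0 RNA reads for 127 of 310. The size of this difference depended on the treatment of 0 reads: it was -1.46, against -0.57 with a pseudocount of 5 and -0.31, at percentile 0.32, with 0 RNA reads set at 3 reads. ZNF280A, next to PRAME on chromosome 22, was at 9834 with 3 RNA reads, and ZNF28 at 2428, ZNF250 at 2160 and ZNF160 at 1564 had 0 RNA reads. Haem synthesis genes (percentile 47.7), erythroid genes (69.4), snoRNA host genes (93.4), small nucleolar RNAs (47.5), small nuclear RNAs (4.62) and the K562 list (66.1) lay within the central 95% of random lists. With a pseudocount of 5 the small nuclear RNAs were at percentile 0.35, outside it.

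**Figure D4:**
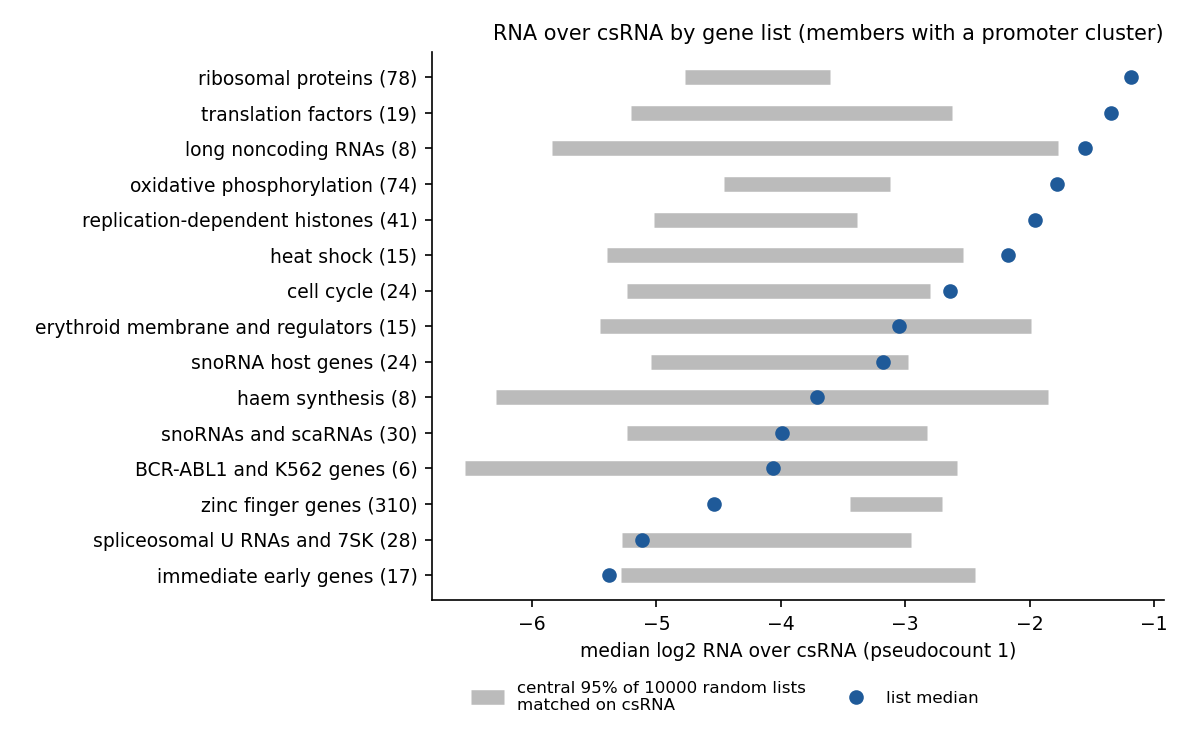
Median log2 RNA over csRNA (pseudocount 1) of each gene list with at least 5 members that had a promoter cluster, with the number of such members in brackets; grey bars are the central 95% of 10000 random lists matched on csRNA level. Ribosomal protein genes lie at -1.19, to the right of their bar, and zinc finger genes at -4.54, to the left of theirs.

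Among the 4729 genes at or above the median csRNA value, RN7SL2, the RNA of the signal recognition particle, had the highest RNA over csRNA, with an RNA value of 87617 and a csRNA value of 2674, a 32.8-fold excess of RNA (exact 95% interval 27.5 to 39.3). TERC, the RNA of telomerase, followed at 7.80-fold (4.23 to 15.99), then ERVE-5, an endogenous retrovirus (5.27-fold), PPIA, which encodes cyclophilin A (4.07-fold), the histone gene H2AC7 (3.90-fold), TMSB4X, which encodes thymosin beta 4 (3.80-fold), NDUFA1 of respiratory complex I (3.67-fold) and GSTP1, a glutathione transferase (3.60-fold). RN7SL2, PPIA, TMSB4X and H2AC7 have near-identical copies in the genome and their values are uncertain.

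The 8 genes that the pseudocount of 1 put at the other end had 0 RNA reads, so their ratios are lower bounds against a floor of 3 reads (an RNA value of 37.05). They are not shown to be the lowest: among genes with RNA reads, csRNA over RNA was 1293-fold at SNORD43 (exact 95% interval 505 to 4749), 802-fold at RNU5A-1 and 265-fold at ZNF280A, above most of these bounds. GADD45B, a stress-induced gene (chromosome 19, 2476052 to 2476202), had a csRNA value of 19626 (95% interval 18401 to 20913), at least 530-fold above the RNA floor. SNORD3F, a copy of the U3 RNA gene whose value is uncertain, was at least 290-fold above it. EGR1, the antiproliferative gene TOB1 (3497, at least 94.4-fold), the inhibitor of differentiation ID2 (2736, at least 73.8-fold), DEDD (2469, at least 66.6-fold), ZNF28 (at least 65.5-fold) and SPDYC (2366, at least 63.9-fold) made up the rest. RNA and csRNA come from different libraries scaled separately, so equal values are no dividing line. Among long noncoding RNAs, KCNQ1OT1 had a csRNA value of 1440 against an RNA value of 74.1. Its log2 ratio of -4.26 lay below the median of all genes, -3.22. NEAT1 (699 against 161, log2 ratio -2.12), MIR17HG (494 against 247, -0.996) and NORAD (267 against 716, 1.42) lay above that median.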

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

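The comparisons in this part were chosen after the values were seen. The table also gave csRNA, input and RNA values on the strand opposite to each cluster, and some of the largest lay at genes with no cluster of their own in the table used here. Of 565 clusters with at least 50 csRNA reads on the opposite strand, 12 had no listed cluster on that strand within 700 bp, and in 10 of the 12 the opposite-strand input exceeded the csRNA.

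Opposite-strand csRNA exceeded input in the other 2. Beside SLC3A2 (chromosome 11, 62856086 to 62856236) it was 4279.15, 9.14 times the input, where the snoRNA host gene SNHG1 and the snoRNA gene SNORD25 lie. Beside PARP2 (chromosome 14, 20343541 to 20343691) it was 2674.47, 4.0 times the input, where RPPH1 lies, the RNA of RNase P, with an opposite-strand RNA value of 24590. SNHG1 was among the host genes without a promoter cluster, and the cause was not tested. Whether the reads beside SLC3A2 belong to SNHG1 or to SNORD25 was not tested, so a start at SNHG1 is not shown.

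The largest opposite-strand input values were at microRNA genes: 297137.09 at MIR148A, 158111.12 at MIR142 and 134719.45 at the NSRP1 cluster, where MIR423 and MIR3184 lie. At MIR148A the opposite-strand csRNA was 2510 and at MIR142 1522, below input in both. At RNY5, a Y RNA gene, csRNA was 73733 against an input of 100307. The largest opposite-strand RNA values were 120185.66 at the GSTA4 cluster, where the 7SK gene RN7SK lies, 99102.84 at RPS29, where RN7SL1 lies, and 87616.59 at a cluster facing RN7SL2. These 3 genes had listed clusters of their own, and the last 2 values are the RNA values of the RN7SL1 and RN7SL2 clusters seen from the other strand. These RNAs have near-identical copies, so the values of single copies are uncertain.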

How the results depend on the processing

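The alternatives called added below were chosen after the result was seen. No paired analysis was possible because the table held no column per library, and no result came from a test. For the same reason the count test by library was not run with any of its alternatives (size factors, low-count filter, replicate number as a block, each replicate left out), and the study of sequence at start sites was not run with any of its own, for want of a genome. Outside the gene lists 40 alternatives were run for 11 results, 11 of them left the value the same and 29 moved it. No direction reversed. The number of clusters, the proximal share and the proximal over distal fold held under all their alternatives, of which the 500 bp limit restates the authors' class and could not differ. Most clusters held few reads, so depth may limit the stable and bidirectional shares: these were 17.5% and 56.1% of distal clusters above the median csRNA. The bidirectional share of distal clusters was lower again at 32 or more reads.

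The median log2 of csRNA over input, 5.97, was 6.96 with a pseudocount of 0.5, 4.13 with 5, 6.96 in clusters above the median csRNA and 3.94 in clusters with input (added). The pseudocount and the choice of clusters set these by construction. The median log2 of RNA over csRNA, -3.22, was -2.99 with a pseudocount of 5, -3.41 above the median csRNA, -7.18 with RNA within the cluster (added) and -2.32 with 0 at 3 reads (added). The stable share was 37.5% of proximal and 4.54% of distal clusters (32.9 points apart) at 2 or more RNA reads, 61.3% and 17.5% (43.8 points) above the median csRNA, and 78.0% and 28.6% (49.3 points) at 32 or more csRNA reads (added). The bidirectional share was 46.6% and 15.5% (31.1 points) for a partner cluster within 300 bp, 57.6% and 18.1% (39.5 points) within 500 bp, 83.4% and 56.1% (27.2 points) above the median csRNA, and 69.7% and 28.6% (41.1 points) at 2 or more opposite-strand reads (added). Apart from these stricter definitions, the cause was not tested.

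Of 90 alternatives for 30 gene-list results, 86 left the call the same and none reversed it. A reversal was counted only for lists outside the central 95%. Lists inside it could change sign, as the erythroid ratio did from 0.39 to -0.41 with 0 RNA reads at 3 reads (added). Against matched random lists, immediate early genes lay at -1.67, and at -1.23 with a pseudocount of 5 and -0.85 with 0 RNA reads at 3 reads (added), both inside the central 95%. Cell cycle genes lay at 1.26, and at 0.72 with 0 RNA reads at 3 reads (added), also inside. Zinc finger genes kept their side at -1.46, -0.57 and -0.31 under the same settings. Small nuclear RNAs lay at -1.05, inside, and at -1.14 with a pseudocount of 5, outside. Only the pseudocount or the treatment of 0 reads differs, and why these lists depend on it was not tested.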

Other observations

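The comparison of other lists around distal clusters, the run test on chromosome 22 and the test inside small nucleolar RNAs were chosen after the result was seen. Distal start sites gathered around erythroid genes. The 15 erythroid genes with a promoter cluster had a mean of 3.33 distal clusters within 50 kb, against 1.2 in random lists of the same size and matched gene length (central 95% 0.533 to 2.07), at percentile 100. ANK1, the ankyrin of the red cell membrane, had 7, EPB41 and GFI1B had 6 each, and LMO2 and TFRC 5 each. Without ANK1 the mean was 3.07, at percentile 99.98. Histone genes (2.83, percentile 100) and immediate early genes (2.94, percentile 99.94) also had more, haem synthesis genes did not (percentile 76.1), and oxidative phosphorylation genes (0.905, percentile 1.97) and zinc finger genes (percentile 0.005) had fewer. Neighbouring members of a list share distal clusters, as H2AC11 and H2AC12 do on chromosome 6 (clusters from 27132968 and 27147031). The random lists were not matched on this, so percentiles of lists with neighbouring members, such as histone genes, may be too extreme.

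On chromosome 9, the 5.84 Mb between FOCAD and CAAP1 (20995951 to 26840684) had 2 clusters. It holds 25 protein-coding genes, including CDKN2A, MTAP and the interferon genes IFNA1 and IFNB1. The promoters on either side had clusters of few reads, with csRNA values of 164.58 at FOCAD and 123.44 summed over 2 clusters at CAAP1, where 1 read is 20.57. A cluster of 161 reads lay between them (22302978 to 22303128, 3312, focus ratio 0.994), at least 82.6-fold above the input floor and 143771 bp from DMRTA1, and the other, of 5 reads, overlapped the 7SK pseudogene RN7SKP120. No copy number was measured here. Whether the 25 genes would be transcribed in K562 was not checked, and a gene that is not transcribed would lack a cluster at any copy number.

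On chromosome 22, the 96 proximal clusters up to BCR had a median csRNA value of 308.59, 1.88 times that of all proximal clusters (1.5 to 3.13), against 102.86 in the next 96 beyond it. Intervals in this paragraph redraw single clusters as if independent, which neighbouring clusters are not, so they may be too narrow. K562 carries extra copies of sequence near the BCR-ABL1 fusion, so copy number may contribute: antisense promoter clusters of the region were 2.17-fold above all such clusters, but the interval (1.0 to 4.17) reaches no difference, and its distal clusters were not higher (0.75-fold). Without its 10 highest clusters, among them PRAME and ZNF280A, the region was 1.75-fold (1.19 to 2.19), but a median responds little to its highest members, so a part played by a few active genes could not be judged. Runs of as many neighbours elsewhere were as high in 0.301% of cases (36 of 11949). These runs moved by 1 cluster at a time and so overlap, and those as high lay on 2 chromosomes. The percentage is therefore not a probability from separate cases. The highest run was on chromosome 1 (40862291 to 46719179, 349.74), and the chromosome 22 region was picked for its values. The highest medians lay at 19 to 21 Mb (308.59, 349.74 and 514.32 in the successive bins of 1 Mb). The 7 and 4 clusters at 22 and 23 Mb, nearest BCR, had medians of 185.16 and 205.73. At 17 and 18 Mb, 10 and 3 clusters had medians of 216 and 123.44, against 164.58 for all proximal clusters. The cause stays open.

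Start sites that lay inside small nucleolar and other small RNA genes may be carry-over of processed small RNA and not new starts. Among clusters with input, the median csRNA over input was 6.32 at 14 inside such genes against 31.1 at 23 at their annotated 5′ ends, a ratio of 0.203 (0.085 to 0.533). Intervals here redraw single clusters. Whether few reads lie behind this could not be told: over all 15 and 35 clusters the inside ones held 2.35 times as many csRNA reads at the median, with an interval of 0.1 to 10, and among those with input the medians were 216 and 153 reads. Ratios overlapped: inside clusters ran from 2.47 at SNORD95 to 86.4 at RNU5D-1, and those at 5′ ends from 2.54 at SCARNA16 to 200 at RN7SL2. Small nucleolar and Cajal body RNA genes made up 13 of the 15 inside clusters and 13 of the 35 at 5′ ends. The comparison therefore does not separate position from kind of gene.

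No cluster lay at the alpha- and gamma-globin promoters, although K562 is known to express these genes. Reads shared between near-identical copies may be a reason: of 32 other genes with such copies 1, GTF2H2C, had a promoter cluster, 3.13% (0.554 to 15.7%) against 39.9% of protein-coding genes. Whether K562 transcribes these 32 genes was not checked, and a gene that is not transcribed would lack a cluster too. Other genes with close copies did have clusters, among them 41 of 68 histone genes, 28 of 49 genes of the small nuclear RNA list (which also holds 7SK, 7SL, U7 and RMRP), HSPA1A (8867) and HSPA1B (1564), which goes against this reason as a general one. How reads with several matches were handled is not given in the sources used here, so the explanation stays open.

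Depth may account for part of the unstable class at sense promoters. The stable share of sense promoter clusters was 35.2 percentage points higher (30.7 to 39.4) at 32 or more csRNA reads than at 2 to 3 reads. That interval subtracts the ends of the Wilson intervals of the shares. More active promoters may also make more RNA, and this test does not separate depth from activity. Antisense promoter clusters were 24.3% stable at 32 or more csRNA reads (7.65% at 2 to 3), against 88.8% of sense promoter clusters. The 2 classes thus differed among clusters with many csRNA reads too. RNA-seq depth was the same in every bin, so these shares cannot judge its part in the antisense class.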
